A study of Mus musculus with 28 samples.

How the data were processed

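The series measured transcripts of inflammation genes in porous polycaprolactone scaffolds implanted under the skin of 28 female BALB/c mice, 14 healthy and 14 inoculated with 4T1 cells, a mouse mammary carcinoma line. The scaffold fills with host tissue and immune cells and is called a synthetic niche in the labels. Scaffolds were taken 7 days (3 healthy, 3 tumor-bearing), 14 days (8 and 8) and 21 days (3 and 3) after inoculation, 1 sample per mouse, per the labels. The labels list the tumor cell line for the healthy mice too, and the condition at the time of analysis was used to form the groups. Replicate numbers run from 1 to 28 through all groups, so no number is shared between groups and the mice are not paired.

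Per the labels' protocols, frozen scaffolds were homogenized, RNA was isolated with DNase treatment and reverse transcribed, and cDNA was run on the TaqMan OpenArray Mouse Inflammation Panel on a QuantStudio 12K Flex instrument. The labels name 7 physical panels, called A to G here. Panels A, B, C, E and F hold samples of both conditions, while panel D holds 4 day 14 healthy samples and panel G holds 4 day 14 tumor-bearing samples. This leaves 10 pairs of a tumor-bearing and a healthy sample of the same day on the same panel, 3 at day 7, 4 at day 14 and 3 at day 21. The software that called the quantification cycles and the number of cycles run are not given in the sources used here.

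Per the file headers, the authors provided raw quantification cycles (Cq), the PCR cycle at which a reaction crosses its detection threshold, so a lower Cq means more template. The deposited normalized values are ratios on a linear scale. The reference genes are not named in the header, and the authors' normalization was used as it stands. The authors' table of comparisons holds fold changes of tumor-bearing over healthy mice for each day, per the file headers, which equal 2 to the power of the difference of the group means of the log2 normalized values. These fold changes come with no errors or p-values and were only set beside the estimates made here.

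All tests used the log2 of the authors' normalized ratios, which is minus the delta Cq. The panel has 648 assays for 584 genes, and 50 genes have several assays. Assays were matched to current gene symbols through RefSeq transcript accessions; 618 assays matched 1 gene and 21 symbols differed from those in the table. Symbols are printed as the table gives them, with the current one beside it where the table's is old. Reactions without a Cq were left missing. An assay was tested where at least 50% of the samples of at least 1 group had a value, which 609 assays met, and where each group of the contrast had at least 2 values.

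The main model was limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a constant prior), with 1 mean per group over all 28 samples, so that days 7 and 21 share the estimate of the spread with day 14. The panel entered as a random block through duplicateCorrelation (statmod 1.5.0), with an estimated correlation within panels of 0.054. Contrasts were tumor-bearing minus healthy at each day and as the mean of the 3 days, the differences of this effect between days, and the changes between days within each condition. P-values were adjusted by Benjamini-Hochberg within each contrast, and an adjusted p under 0.05 counts as past the threshold. Every adjusted p of a single gene comes from this limma model unless another test is named, and ± after a log2 difference is its standard error.

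The genes named were set by a rule. It takes the 12 largest rises and the 12 largest falls past the threshold with a value in every sample of the groups compared, or the 6 smallest p-values where fewer than 5 assays pass. For differences between days and time courses it takes 6 genes per direction past the threshold, or the 3 smallest p-values. Members of the gene lists past the threshold, or the 2 smallest p-values of a list, are named with their list. Pglyrp1, F3, Ghrl, Bmp15 and the second S100a8 assay fall outside this rule and were chosen after their values were seen.

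Gene lists were 22 sets of textbook markers and pathway genes written without reference to the values. Of these, 20 had at least 5 measured members and were tested: neutrophil and granulocytic cell markers, monocyte and macrophage markers, alternative macrophage activation, classical inflammatory activation, T cell markers, dendritic cell and antigen presentation, mast cell, basophil and eosinophil markers, neutrophil-attracting chemokines and growth factors, monocyte- and eosinophil-attracting CC chemokines, lymphocyte-attracting chemokines, interferon response, IL-1 family and inflammasome, Toll-like receptor and NF-kappaB pathway, complement, eicosanoid synthesis and receptors, extracellular matrix, fibroblast and remodelling, endothelial cells and leukocyte adhesion, immune checkpoint and suppression, epithelial and tumor cell markers, and housekeeping genes. The cytotoxic and NK cell markers had 4 members on the panel and the B cell markers 2, and these were left untested. Each list was tested against all other genes with cameraPR of limma on the moderated statistics, 1 assay per gene, with a preset inter-gene correlation of 0.01 and again with the correlation estimated from the residuals, adjusted over the lists of a contrast. The fry test of limma, which asks whether the members of a list move in 1 direction on balance, was run on the members measured in all 28 samples. Whether an assay gave a Cq at all was compared between conditions with Fisher's exact test, two-sided.

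The model, the lists, the naming rule and most alternatives were fixed before the data were examined. These alternatives were no panel block, the panel as a fixed block, day 14 without or with only panels D and G, raw Cq centred on each sample's median or on 12 housekeeping genes, missing reactions set to the largest Cq, assays measured in all samples, no detection filter, a mean Cq of at most 28, another prior of eBayes, a separate model per day, and each sample left out in turn. After seeing the data, 2 more were chosen: without the reactions more than 4 cycles from the median of their own group, and without the 4 samples with the most missing or outlying reactions. Other splits of the samples into groups of the same sizes were also tested, at most 100 per contrast.

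The procedure was tested on simulated data with the real missing values and spread. At day 14 it called 78.1% of assays given a log2 change of 1, 89.2% of those given 2 and 95.4% of those given 4, and 8 of 394 unchanged assays. At day 21 these shares were 50%, 79.4% and 98.4%, with 5 of 385 unchanged assays called. At day 7, where no change was simulated, 0 of 565 assays were called. The changed assays were 64, 65 and 65 of the 588 tested at day 14, whereas the real data gave 14 calls there. Where so many assays change, the Benjamini-Hochberg cutoff is looser. The shares called therefore do not give the power for the real data and may be too high for it. A list shifted by 1 had an adjusted p of 4.71e-18, and 0 of the other lists were called. The simulated genes varied independently of each other, whereas the correlation estimated for the neutrophil list at day 14 was 0.16. The simulation therefore does not show how often the list test errs with correlated genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.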

Results

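Of 18144 reactions, 2244 (12.4%) gave no Cq. A value was present in all 28 samples for 312 assays and in no sample for 9. The raw Cq had a median of 21.8 and ran from 3.654 to 39.699. Day 7 healthy samples had a median of 572 assays with a value and day 7 tumor-bearing samples 569. At day 14 the medians were 570.5 (475 to 586) in healthy and 582.5 (489 to 586) in tumor-bearing mice, and at day 21 they were 582 and 572. Within groups, the Spearman correlation of samples over assays was 0.905 to 0.993. The number of mice limits the precision: the median standard error of a tumor-bearing minus healthy log2 difference was 0.36 at day 7, 0.25 at day 14 and 0.36 at day 21.

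The series follows how a tumor growing elsewhere in the body is reflected in the implant, with a focus on myeloid cells. The comparison at day 14, with 8 mice per condition, is the largest. At this day, transcripts of neutrophil granule proteins were higher in the implants of tumor-bearing mice. Camp, which encodes the antimicrobial peptide precursor of neutrophil granules, rose 28-fold in the model with the panel block (95% interval 9.75 to 80.4). Its plain mean log2 relative quantity was -10.07 ± 1.96 (SD, n = 7) in healthy and -5.38 ± 1.65 (SD, n = 8) in tumor-bearing mice. The granule proteases of early neutrophils rose too, Prtn3 (proteinase 3) 21-fold and Ela2 (now Elane, neutrophil elastase) 13.1-fold. The calcium-binding proteins S100a9 and S100a8, abundant in the cytoplasm of neutrophils, rose 4.34-fold and 3.62-fold.

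In the limma model, 14 of 588 assays, for 13 genes, passed the threshold at day 14, 10 higher and 4 lower in tumor-bearing mice, and 62 had an unadjusted p under 0.05. The count was 8 without healthy replicate 11 or without tumor-bearing replicate 22. Of the 11 measured neutrophil and granulocytic cell markers, 8 rose and 0 fell, and 8 rose when adjusted over the list alone. The list shifted by a mean log2 difference of 2.06 (adjusted p = 5.03e-23 with the preset correlation, adjusted p = 1.12e-10 with an estimated correlation). Camp differed by 4.81 ± 0.73 (adjusted p = 0.000408) and was higher in all 4 panel-matched pairs. Prtn3 differed by 4.39 ± 0.8 (adjusted p = 0.00588) and Ela2 by 3.71 ± 0.76 (adjusted p = 0.00924), each higher in 2 of 2 pairs. Prtn3 gave a Cq in 8 of 8 tumor-bearing and 3 of 8 healthy samples. S100a9 differed by 2.12 ± 0.38 (adjusted p = 0.00212) and S100a8 by 1.85 ± 0.46 (adjusted p = 0.0285), each higher in 4 of 4 pairs, with 2.17 ± 0.5 in its second assay. The lactoferrin gene Ltf (2.28 ± 0.59, adjusted p = 0.038), the formyl peptide receptor gene Fpr1 (1.40 ± 0.3, adjusted p = 0.00924) and Il8rb (now Cxcr2, a receptor for neutrophil chemokines; 1.39 ± 0.26, adjusted p = 0.00347) complete the list's calls, higher in 3 of 3, 4 of 4 and 3 of 3 pairs. Pglyrp1, a peptidoglycan recognition protein of neutrophil granules outside the list, rose 3.15-fold (adjusted p = 0.000408), higher in 3 of 3 pairs. The median log2 difference of all assays was -0.084 at day 14, and 0.027 with raw Cq centred on each sample's median.

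The separation between mice was uneven. All 8 tumor-bearing samples with a value of Prtn3, and all 7 of Ela2, lay above every healthy sample with a value, as did 7 of 8 for S100a9, 6 of 8 for Camp and 4 of 8 for Ltf. S100a9 had its lowest group mean in day 14 healthy mice, at -1.85 ± 0.95 (SD, n = 8), against -0.61 ± 0.54 (SD, n = 3) at day 7 and -0.05 ± 0.61 (SD, n = 3) at day 21 in healthy mice, and tumor-bearing mice had 0.23 ± 0.87 (SD, n = 8) at day 14.

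**Figure D1:**
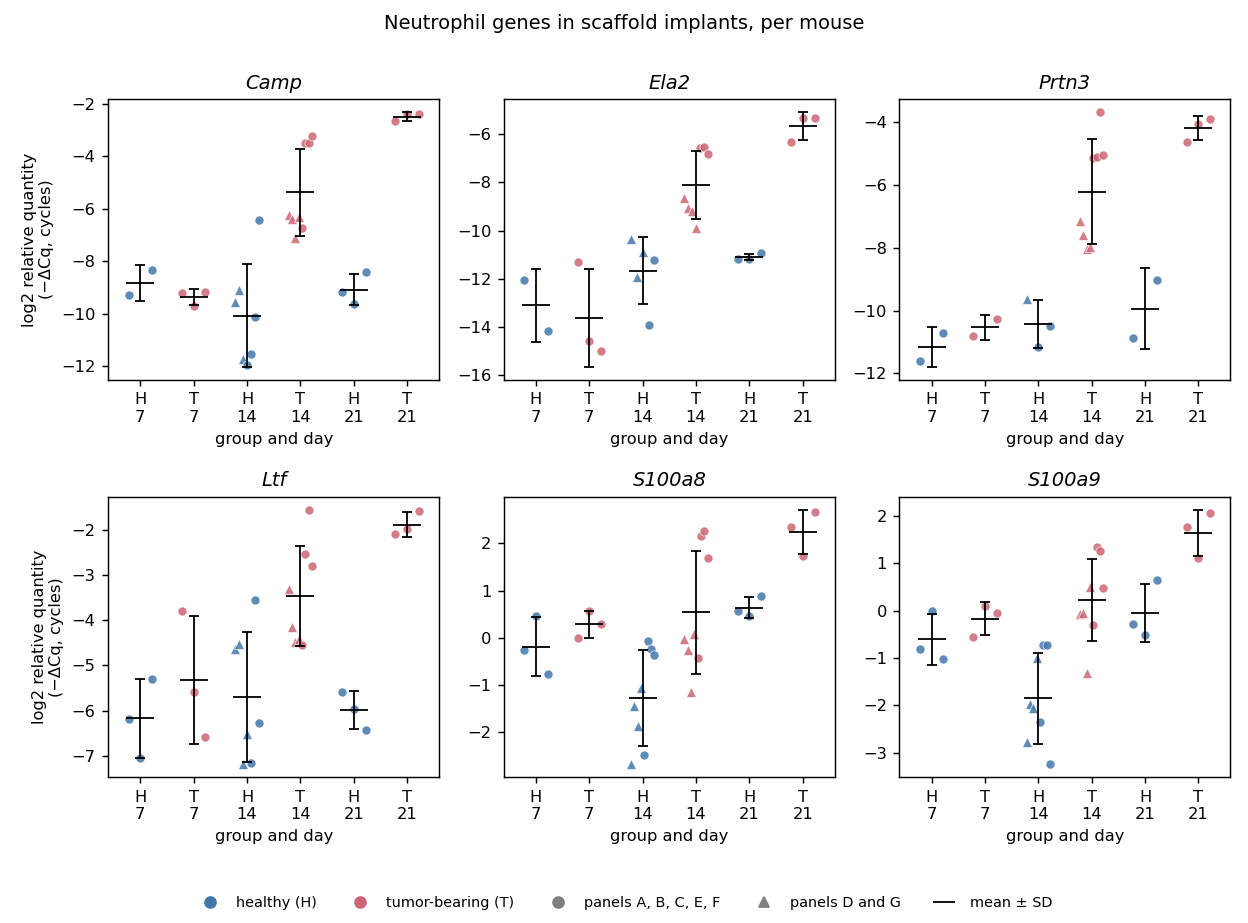
Log2 relative quantity (minus delta Cq, in cycles) of 6 neutrophil genes in each mouse by condition (H healthy, T tumor-bearing) and day, with mean ± SD; triangles are samples on panels D and G, and mice without a Cq have no point. For Camp, the mean of tumor-bearing mice is -9.36 at day 7, -5.38 at day 14 and -2.5 at day 21.

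The 4 genes lower in tumor-bearing mice at day 14 were members of none of the lists, and none of them passed with the panel as a fixed block (F3 -1.05, adjusted p = 0.211; Ltbp4 -0.97, adjusted p = 0.161; Bmp15 -1.29 and Ghrl -3.46, adjusted p = 0.42 for both). Without panels D and G, F3 passed (-1.05, adjusted p = 0.014), and Ltbp4 (adjusted p = 0.121) and Bmp15 (adjusted p = 0.197) did not. F3, the tissue factor gene that starts coagulation, fell to 0.552-fold (log2 difference -0.86 ± 0.21, adjusted p = 0.0285), lower in 3 of 3 panel-matched pairs. Within healthy mice F3 also fell from day 14 to day 21. That fall did not pass in the main model but passed with no panel block (-1.13, adjusted p = 0.0391) and in some other settings. Ltbp4, a binding protein of latent TGF-beta, fell to 0.582-fold (-0.78 ± 0.21, adjusted p = 0.046), lower in 4 of 4 pairs, and its second assay did not pass (-0.68, adjusted p = 0.171). With 1 mouse left out, Ltbp4 passed in 4 of 16 models, Ghrl in 7, F3 in 12 and Bmp15 in 15, and of the rises Ltf passed in 8 and the S100a8 assays in 11 and 14. The growth factor gene Bmp15, known from the ovary (-1.90 ± 0.42, adjusted p = 0.017; lower in 4 of 4 pairs) and the ghrelin gene Ghrl (-1.90 ± 0.45, adjusted p = 0.0408, 5 tumor-bearing against 4 healthy values) also fell, and their estimates turn positive, at 0.48 and 0.57, when missing reactions are set to the largest Cq.

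No other list passed at day 14. The T cell markers had a mean of -0.51 (adjusted p = 0.301), with Foxp3 at -1.07 (adjusted p = 0.243) and Icos at -0.86 (adjusted p = 0.307). The alternative macrophage activation genes had a mean of 0.13 (adjusted p = 0.57), with Chi3l3 (now Chil3, a chitinase-like protein of activated macrophages and neutrophils) at 1.53 (adjusted p = 0.079) and Ccl22 at -0.53 (adjusted p = 0.155), each past the threshold when adjusted over the list alone. Monocyte and macrophage markers had a mean of 0.08 (adjusted p = 0.57), and Toll-like receptor and NF-kappaB pathway genes 0.02 (adjusted p = 0.301). The epithelial and tumor cell markers had a mean of -0.85 (adjusted p = 0.712), with the keratin gene Krt8 at -3.64 (adjusted p = 0.196). Krt8 passed when adjusted over the list alone, and without the reactions more than 4 cycles from their group median (-4.70, adjusted p = 0.00725). At day 14 the latter setting removes the Krt8 value of healthy replicate 9, which came 4.59 cycles later than its group median. Krt8 had values in 5 healthy and 6 tumor-bearing samples, and 1 tumor-bearing value lay below every healthy one. Dendritic cell and antigen presentation genes had a mean of -0.24 (adjusted p = 0.712), with Ccr7 at -0.64 (adjusted p = 0.0792) and 2 lower when adjusted over the list alone. The adjusted p was 0.747 to 0.956 for the housekeeping (mean -0.03), classical inflammatory (-0.34), interferon (-0.11), IL-1 family (-0.02), lymphocyte-attracting chemokine (0.02), CC chemokine (0.05), mast cell (-0.20), checkpoint (-0.22), endothelial (-0.07), extracellular matrix (-0.11), eicosanoid (-0.23), neutrophil-attracting chemokine (-0.36) and complement (-0.09) lists.

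In the 4 samples per condition on panels with both conditions, the neutrophil list shifted by 2.66 and Camp by 5.78 (adjusted p = 0.00495), and on panels D and G alone the list shifted by 1.32 (adjusted p = 1.01e-12) with Camp at 3.63 (adjusted p = 0.194) and 0 assays past the threshold in limma. Ela2 stood at 5.89 (adjusted p = 0.0111) and Prtn3 at 6.09 (adjusted p = 0.000146) without panels D and G, and Ela2 at 1.85 (adjusted p = 0.391) on these alone. Without healthy replicate 12, Ela2 stood at 3.06 and Prtn3 at 3.98. With missing reactions set to the largest Cq, 4 assays passed, and the neutrophil list stood at 3.84. With the panel as a fixed block the rises of Ltf (2.81, adjusted p = 0.211) and Fpr1 (1.38, adjusted p = 0.161) did not pass. Over all alternatives the adjusted p of Camp was 0.000221 to 0.224.

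At day 21, with 3 mice per condition, the same granule genes showed the largest differences among the genes past the threshold. Camp rose 96.2-fold (95% interval 19.4 to 476), from -9.08 ± 0.6 (SD, n = 3) in healthy to -2.5 ± 0.16 (SD, n = 3) in tumor-bearing mice. Prtn3 rose 54-fold, Ela2 43.4-fold and Ltf 17.2-fold. Chi3l3 rose 8.99-fold and Itgb2l, an integrin subunit gene of neutrophils, 9.42-fold. Ccr7, the receptor that guides dendritic cells and T cells to lymph nodes, fell to 0.442-fold.

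The limma model called 7 of 573 assays at day 21, 6 higher and 1 lower, with 52 at an unadjusted p under 0.05. Camp differed by 6.59 ± 1.11 (adjusted p = 0.00338), Prtn3 by 5.76 ± 1.06 (adjusted p = 0.0103) and Ela2 by 5.44 ± 1.01 (adjusted p = 0.00998). Ltf differed by 4.10 ± 0.88 and Chi3l3 by 3.17 ± 0.69 (adjusted p = 0.0137 each), and Itgb2l by 3.24 ± 0.7 (adjusted p = 0.0437). Camp, Ela2, Ltf and Chi3l3 were higher in 3 of 3 panel-matched pairs, Prtn3 and Itgb2l in 2 of 2. Ccr7 differed by -1.18 ± 0.3 (adjusted p = 0.0437) and was lower in 3 of 3 pairs. For each of these 7 genes the measured mice of the conditions did not overlap, which chance gives in 10% of genes with 3 against 3 mice, and more often for Prtn3 and Itgb2l with 2 healthy values. Of the 12 neutrophil markers, 5 rose and 0 fell (6 rose when adjusted over the list alone), and the list's mean log2 difference was 2.50 (adjusted p = 8.8e-15 with the preset correlation, adjusted p = 9.76e-08 with an estimated correlation). The list did not pass with fry on 5 members (adjusted p = 0.234), nor with assays measured in all 28 samples, where its mean was 0.73. S100a9 at 1.70 (adjusted p = 0.268) and S100a8 at 1.61 (adjusted p = 0.495) did not pass.

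Other lists moved down at day 21 with the preset correlation. Classical inflammatory activation had a mean of -0.76 over 18 genes (adjusted p = 0.00122), with Ccl5 at -1.09 (adjusted p = 0.109) and Il12b at -1.88 (adjusted p = 0.262). The 14 lymphocyte-attracting chemokines had a mean of -0.62 (adjusted p = 0.00421), with 2, Ccl22 (-1.14, adjusted p = 0.073) and Ccl5, lower when adjusted over the list alone. Dendritic cell and antigen presentation genes had a mean of -0.37 (adjusted p = 0.0374), with 1 of 8, Ccr7, past the threshold and 2 when adjusted over the list alone. All of these calls were lost with an estimated correlation, at an adjusted p = 0.157 for each. The lists overlap, so their shifts are not separate results. The classical list shares Ccl5, Cxcl9, Cxcl10 and Cxcl11 with the lymphocyte-attracting list, and Cd40, Cd80 and Cd86 with the dendritic cell list. Ccl22 is in both the lymphocyte-attracting and the dendritic cell list. Without tumor-bearing replicate 27 or 28, 2 lists passed instead of 4. Monocyte and macrophage markers had a mean of 0.35 (adjusted p = 0.0542), with Ccr2, the receptor of inflammatory monocytes, at 0.78 (adjusted p = 0.533). Neutrophil-attracting chemokines and growth factors had a mean of -0.64 (adjusted p = 0.0971), with Cxcl2 at -1.86 (adjusted p = 0.31) and Cxcl1 at -0.70 (adjusted p = 0.677). In the alternative activation list, 1 of 14 genes, Chi3l3, rose.

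**Figure D2:**
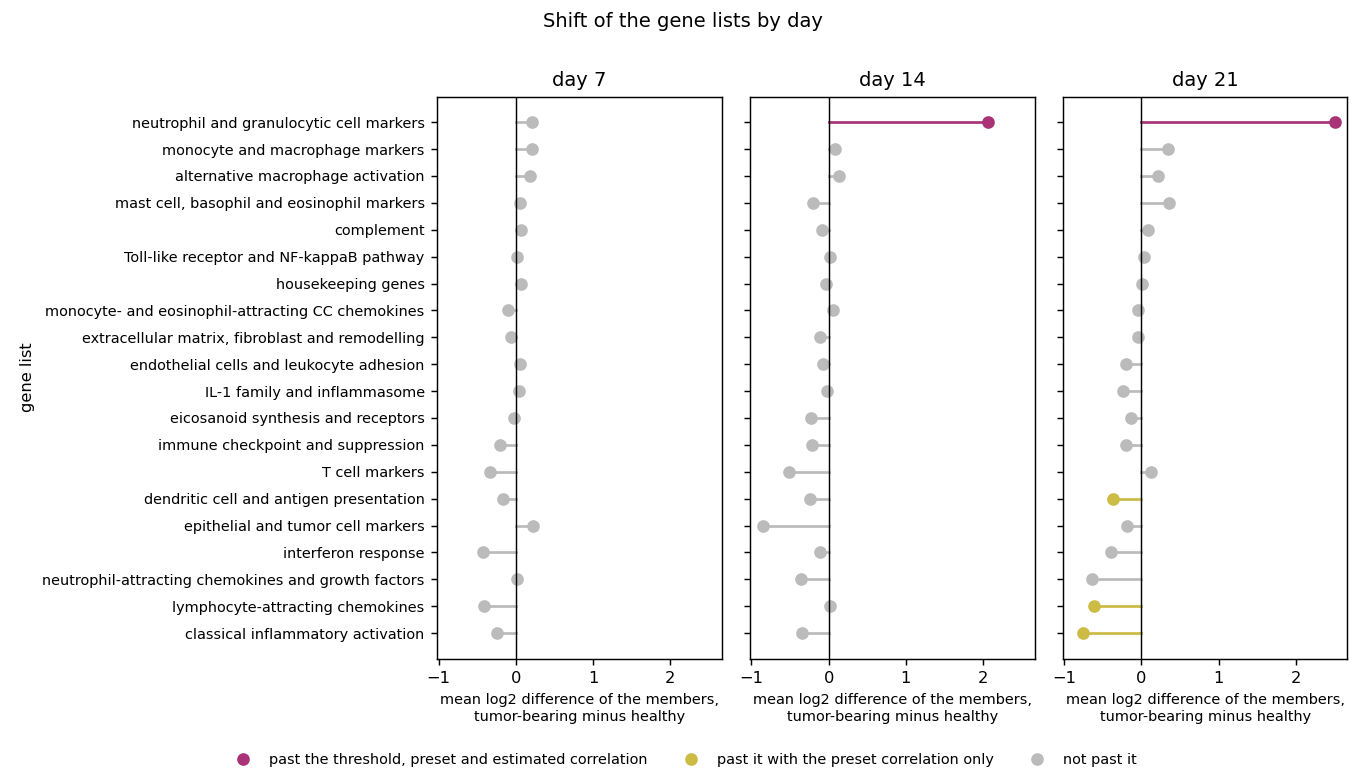
Mean log2 difference (tumor-bearing minus healthy) of the members of the 20 tested lists at days 7, 14 and 21; purple points passed with the preset and with an estimated correlation, yellow points with the preset correlation alone, grey points with neither. The neutrophil list stands at 0.21, 2.06 and 2.50 on the 3 days.

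Leaving out 1 mouse at day 21 gave between 1 call (without healthy replicate 23) and 7 calls, with 3 without replicate 24 or 25. Camp remained past the threshold in all 6 of these models, Ela2 in 5, Chi3l3 in 3, Ltf in 2, Itgb2l in 1 and Ccr7 in 0. Prtn3 passed in all 4 models in which each group still had 2 values. With missing reactions set to the largest Cq, 0 assays passed at day 21, Camp being at 6.59 (adjusted p = 0.367).

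At day 7, with 3 mice per condition, no gene passed. The neutrophil granule genes did not yet stand apart: Camp had a mean of -8.82 (n = 2) in healthy and -9.36 (n = 3) in tumor-bearing mice, and the lactoferrin gene Ltf differed by 0.85 ± 0.88 (adjusted p = 0.997). The smallest p-values belonged to the cytokine genes Il27 (-1.44 ± 0.42) and Ifng (-3.25 ± 0.96, adjusted p = 0.73 for both), to the chemokine receptor gene Cxcr7 (-0.97 ± 0.33), and to P2ry1 (1.03 ± 0.39), Hrh1 (0.89 ± 0.35) and Lepr (-0.67 ± 0.27), each with an adjusted p = 0.997. The second Ifng assay stood at -1.20 ± 0.88.

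The limma model called 0 of 565 assays at day 7, with 12 at an unadjusted p under 0.05. None of the lists passed. Lymphocyte-attracting chemokines had a mean of -0.41 (adjusted p = 0.113), and T cell markers (-0.34), interferon response genes (-0.43) and classical inflammatory genes (-0.25) an adjusted p = 0.133 each. The neutrophil list had a mean of 0.21 (adjusted p = 0.355), which was -0.02 without tumor-bearing replicate 4. Without healthy replicate 3, 3 lists passed.

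Averaged over the 3 days, the neutrophil genes were higher and Ccr7, Ccl22 and Ccl5 lower in tumor-bearing mice. Chi3l3 rose 3.29-fold (log2 difference 1.72 ± 0.36, adjusted p = 0.00618), higher in 9 of 10 panel-matched pairs, and S100a9 rose 2.67-fold (1.42 ± 0.31, adjusted p = 0.00711), higher in 10 of 10. Ccr7 fell (-0.81 ± 0.15, 95% interval 0.457-fold to 0.707-fold, adjusted p = 0.00252), lower in 9 of 10 pairs. Ccl22, a chemokine of dendritic cells and macrophages that attracts T cells, fell to 0.622-fold (-0.69 ± 0.15, adjusted p = 0.00711; 8 of 9 pairs), and Ccl5, a chemokine for T cells and monocytes, to 0.613-fold (-0.71 ± 0.16, adjusted p = 0.0141; 9 of 10 pairs). The second Ccl5 assay stood at -0.55 (adjusted p = 0.186).

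The limma model called 14 of 559 assays for this mean, 10 higher and 4 lower, with 49 at an unadjusted p under 0.05. Camp (3.64 ± 0.61, adjusted p = 0.00212), Prtn3 (3.59 ± 0.58, adjusted p = 0.00252), Ltf (2.41 ± 0.46, adjusted p = 0.00283), Ela2 (2.85 ± 0.57, adjusted p = 0.00618), Fpr1 (0.91 ± 0.24, adjusted p = 0.0436), Il8rb (0.77 ± 0.21, adjusted p = 0.0455), Pglyrp1 (1.10 ± 0.19, adjusted p = 0.00212) and the second S100a8 assay (1.46 ± 0.39, adjusted p = 0.0455) were the other rises. The drug transporter gene Abcb1a was the other fall (-0.44 ± 0.12, adjusted p = 0.0418). Of the 11 neutrophil markers 7 rose (9 when adjusted over the list alone), with a mean of 1.57 (adjusted p = 3.86e-19 with the preset correlation, adjusted p = 8.06e-09 with an estimated correlation). Without day 7 healthy replicate 3, where 8 of the 11 could be tested, its mean was 0.87 (adjusted p = 9.89e-09).

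With the preset correlation, classical inflammatory activation (mean -0.45, adjusted p = 0.00426; 1 of 18 fell), dendritic cell and antigen presentation (-0.26, adjusted p = 0.0183; 2 of 8 fell), lymphocyte-attracting chemokines (-0.34, adjusted p = 0.0183; 2 of 14 fell) and T cell markers (-0.37, adjusted p = 0.0285; 0 of 11 fell) were lower, and monocyte and macrophage markers (0.21, adjusted p = 0.0183; 0 of 9 rose) higher. These calls were lost with an estimated correlation, at an adjusted p = 0.196, 0.184, 0.196, 0.196 and 0.101 in the same order. Of the 6 lists past the threshold, 2 were left without day 21 replicate 27 and 3 without replicate 28. The members that fell were Ccr7, Ccl22 and Ccl5 alone, and the same counts held when adjusted over each list alone. Ccl5 counts in both the classical and the lymphocyte-attracting list, and Ccl22 in both the lymphocyte-attracting and the dendritic cell list. The remaining 14 lists had an adjusted p of 0.382 to 0.923. Leaving out 1 mouse gave 8 (without day 7 healthy replicate 3) to 15 calls, with 9 without day 7 replicate 1, 2, 4 or 5 or day 21 replicate 24 or 28, and Ccr7, Chi3l3, Ltf, Pglyrp1 and S100a9 remained in all 28 such models. Il8rb passed in 7 of them, the second S100a8 assay in 8, Fpr1 in 10, Abcb1a in 13 and Ccl5 in 27. Prtn3 passed in all 22, and Camp, Ela2 and Ccl22 in all 26, of the models in which each group still had 2 values.

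**Figure D3:**
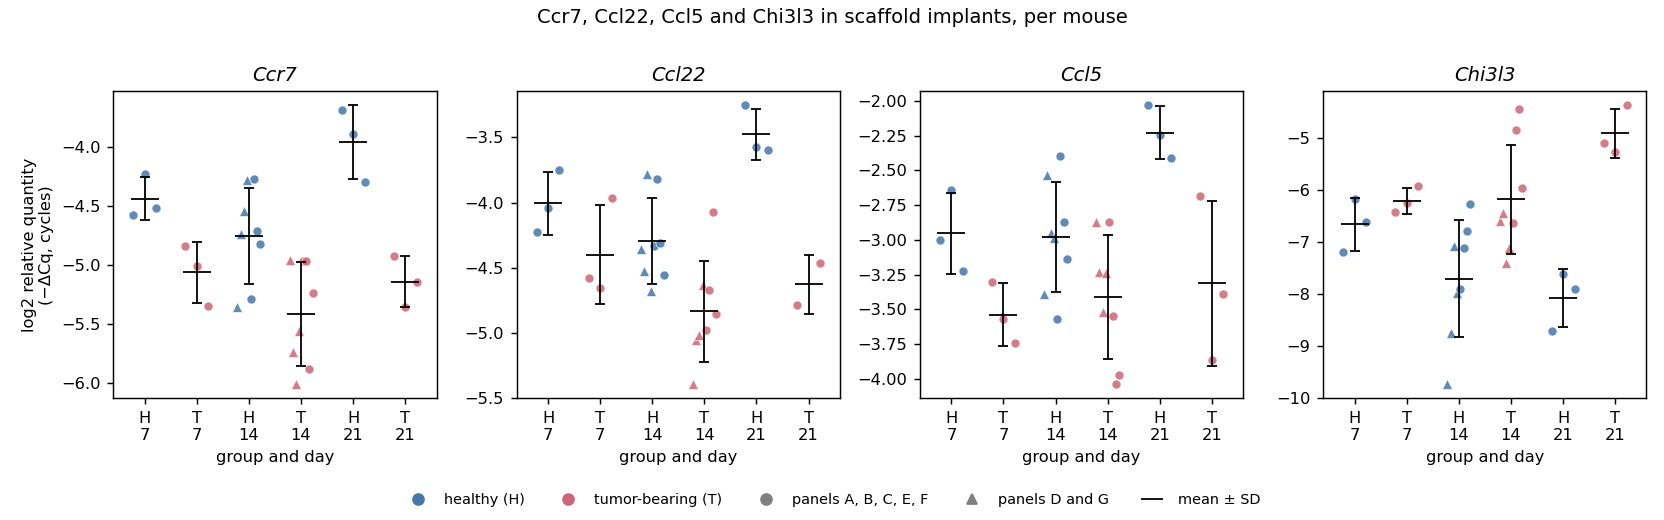
Log2 relative quantity (minus delta Cq, in cycles) of Ccr7, Ccl22, Ccl5 and Chi3l3 in each mouse by condition and day, with mean ± SD, symbols as in the plot of the neutrophil genes. For Ccr7, all 3 tumor-bearing mice lie below every healthy mouse at day 7 and at day 21 (chance separates 3 against 3 mice in 10% of genes), and 4 of 8 at day 14.

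Several lists had a mean, median and test that differed in sign. For T cell markers at day 21 the mean was 0.12, the median -0.42 and the test pointed down. At day 7 such a split occurred for the epithelial, eicosanoid, neutrophil-attracting chemokine and Toll-like receptor lists, and at day 14 for the housekeeping, interferon, IL-1 family, lymphocyte-attracting chemokine, CC chemokine, endothelial, extracellular matrix, eicosanoid and neutrophil-attracting chemokine lists. At day 21 it also occurred for the housekeeping, eicosanoid, epithelial and extracellular matrix lists, and for the mean of the 3 days for the eicosanoid, mast cell, complement and Toll-like receptor lists. None of these lists passed the threshold in those contrasts. In day 21 tumor-bearing replicate 26, the T cell markers Cd40lg and Tnfrsf9 lay -14.96 and -7.03 cycles from their group medians. These early reactions raise that list's mean. Tnfrsf9 stood at 2.22, yet 2 of 3 tumor-bearing mice lay below every healthy one. In day 14 healthy replicate 13, Ppbp of the neutrophil-attracting chemokine list lay -12.73 cycles from its group median. Ppbp stood at -2.23 at day 14, and at -0.52 without outlying reactions.

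Whether the tumor effect changed between days was tested directly, since the series follows disease progression. Of the assays tested, Camp had the largest estimates for both changes from day 7: its tumor-bearing minus healthy difference was 5.29 ± 1.45 larger at day 14 than at day 7 (adjusted p = 0.268) and 7.07 ± 1.67 larger at day 21 than at day 7 (adjusted p = 0.196). For the latter change Ela2 stood at 6.04 ± 1.52 (adjusted p = 0.232) and Prtn3 at 5.12 ± 1.58 (adjusted p = 0.953). Day 14 minus day 7 also had Hrh1 at -1.58 and Il27 at 1.86 (adjusted p = 0.268), and day 21 minus day 14 had Il19 at 2.74, Bmp15 at 2.80 and Fabp4 at 5.05 (adjusted p = 0.478). In the limma model 0 of 564, 0 of 571 and 0 of 560 assays passed for day 14 minus 7, day 21 minus 14 and day 21 minus 7, with 21, 31 and 22 at an unadjusted p under 0.05. With the panel as a fixed block, Camp (6.56 ± 1.35, adjusted p = 0.0479) and Ela2 (6.65 ± 1.15, adjusted p = 0.0357) passed for day 21 minus day 7, and Ela2 (6.62 ± 1.18, adjusted p = 0.0497) for day 14 minus day 7. Leaving out 1 mouse gave 1 call for day 14 minus 7 (without day 14 healthy replicate 14) and 1 for day 21 minus 7 (without day 7 tumor-bearing replicate 4).

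Within tumor-bearing mice, Ela2, Camp and Prtn3 rose between day 7 and day 21, and Ela2 also between day 7 and day 14. Ela2 rose by 5.63 ± 0.88 from day 7 to day 14 (adjusted p = 0.00225) and by 8.00 ± 1.03 from day 7 to day 21 (adjusted p = 0.000148). Camp rose by 6.69 ± 1.13 (adjusted p = 0.00169) and Prtn3, the other protease gene of early granules, by 6.28 ± 1.08 (adjusted p = 0.0049) from day 7 to day 21. From day 7 to day 14, Camp and Prtn3 passed with the panel as a fixed block (4.67, adjusted p = 0.0136, and 5.45, adjusted p = 0.000533) and without panels D and G (5.06, adjusted p = 0.0436, and 5.76, adjusted p = 0.000316). The limma model called 1 of 571 assays for day 14 minus 7, 0 of 583 for day 21 minus 14 and 3 of 567 for day 21 minus 7, with 49, 60 and 50 at an unadjusted p under 0.05. The first count was 2 without replicate 4, 18 or 21 and 3 without replicate 6, 16 or 17, and the second was 9 without replicate 27 and 6 without replicate 28. From day 14 to day 21 the smallest p-values were those of Cxcr4 (a chemokine receptor that retains neutrophils in bone marrow; 5.98), Itgb2l (2.61, adjusted p = 0.0878 for both) and Fabp4 (a fatty acid binding protein of fat cells and macrophages; 4.62, adjusted p = 0.126); the Cxcr4 and Fabp4 estimates turn negative, at -3.12 and -4.26, when missing reactions are set to the largest Cq. At day 21 each of these 2 assays had a value in 2 tumor-bearing mice, with a raw Cq of 6.862 for Cxcr4 and 7.636 for Fabp4 in replicate 26 against 18.948 and 17.002 in replicate 28. The Fabp4 difference of 5.05 given for the tumor effect rests on the same reaction, and the other Fabp4 assay stood at 1.15-fold at day 21 in the authors' table.

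Within healthy mice, which show the implant without a tumor, Reg3g, an antimicrobial lectin gene, rose by 1.91 ± 0.4 and Clec7a, the gene of the fungal glucan receptor dectin-1, by 0.91 ± 0.19 from day 14 to day 21 (adjusted p = 0.0358 for both). Nos2, the inducible nitric oxide synthase gene, had estimates of -1.64 from day 7 to day 14 (adjusted p = 0.222) and -2.06 from day 7 to day 21 (adjusted p = 0.208). The other smallest p-values were those of Gpr17 (1.16, adjusted p = 0.0986) and Ltbp4 (0.97, adjusted p = 0.222) for day 14 minus 7, and of Clec7a (0.91) and Il8ra (now Cxcr1; 1.34, adjusted p = 0.208 for both) for day 21 minus 7. The limma model called 0 of 572, 2 of 578 and 0 of 570 assays for day 14 minus 7, day 21 minus 14 and day 21 minus 7, with 74, 92 and 57 at an unadjusted p under 0.05. The day 21 minus day 14 count ran from 0 (without day 14 replicate 7 or 11, or day 21 replicate 23, 24 or 25) to 15 (without day 14 replicate 12), with 13, 10 and 4 without replicates 13, 10 and 9, and Reg3g and Clec7a did not pass with the panel as a fixed block (adjusted p = 0.167 and 0.182).

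Detection of a Cq was compared between conditions with Fisher's exact test, two-sided. At day 14, Itgb2l gave a Cq in 8 of 8 tumor-bearing and 1 of 8 healthy samples, and 0 of 276 assays passed after adjustment (Itgb2l adjusted p = 0.386), with 3 at an unadjusted p under 0.05. Counting only a Cq of at most 28 as detection, Prtn3 was found in 8 of 8 tumor-bearing and 0 of 8 healthy samples (adjusted p = 0.0378), 1 of 243 assays past the threshold. At days 7 and 21 the smallest p that 3 against 3 mice allow is 0.1. Over all days, 0 of 327 assays passed.

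The authors' fold changes were set beside the estimates across genes, which are not independent replicates. Both come from the same normalized values and group means, so a correlation near 1 follows from how they were computed and is no check of the results. Pearson's correlation of the log2 values was 1 at day 7, 0.998 at day 14 and 1 at day 21, and 100%, 98.8% and 99.7% of assays had the same sign. The authors' table holds 15, 21 and 54 assays over 2-fold at days 7, 14 and 21, of which 0, 10 and 6 passed the threshold here, and 17, 31 and 30 under 0.5-fold, of which 0, 2 and 1 passed. Its largest fold at day 7 was Aif1 at 32.16, which rests on 1 reaction with a raw Cq of 4.499 in replicate 4, and at day 21 Chrna7 at 382800.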

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

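Of the tests in this part, those of panels and of blood for the neutrophil genes, and those of dilution and of panels for Ccr7, Ccl22 and Ccl5, were chosen only after the result was seen.

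In 31 checks, each of 1 assay or sample measure in the day 14 healthy or tumor-bearing mice, the highest or lowest sample was compared with the others. It lay far from them in 4 checks, where chance gives about 1.6 (about 1 in 20 checks). The checks share the same mice and are not independent. Day 14 healthy replicate 13 had 475 assays with a value against 535 to 586 in the other healthy samples, a gap of 0.541 of the whole range. Day 14 tumor-bearing replicate 21 had 489 against 562 to 586, a gap of 0.753. Both ran on panel E, and 37 assays missing in both had a value in all of the other samples. For Bmp15, day 14 healthy replicate 8 stood highest at -8 against -10.02 to -9.36, a gap of 0.673 of the range of 6 values. For Ghrl, day 14 healthy replicate 9 stood lowest at -11.91 against -9.96 to -9.65, a gap of 0.862 of the range of 4 values.

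The higher neutrophil gene list at day 14 (mean log2 difference 2.06) was set against technical explanations. A difference between panels is argued against by the samples on panels with both conditions, where the list stood at 2.66 (adjusted p = 8.51e-21). These samples include healthy replicates 13 and 14 and tumor-bearing replicate 21, which had many missing or outlying reactions. The shift was smaller on panels D and G alone, where panel and condition cannot be told apart. The authors' choice of reference genes is argued against by raw Cq centred on each sample's median, with the list at 2.19. More blood in the implants would bring platelets too, but the platelet gene Ppbp differed by -0.52 (95% interval -1.24 to 0.19) without outlying reactions. This single gene speaks only to blood with the same ratio of neutrophils to platelets in both conditions. That ratio was not measured, so blood richer in neutrophils stays possible. A larger number of neutrophils or their precursors in the implants of tumor-bearing mice, or more of these transcripts per cell, stays open as a biological hypothesis, found and tested on the same data.

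Ccr7, Ccl22 and Ccl5 were lower over the 3 days, by a mean log2 difference of -0.74. For dilution of all other cells by neutrophils, the 9 monocyte and macrophage markers were examined. Their mean was 0.21 (95% interval over the 9 genes 0.09 to 0.34), so as a set they did not fall with the 3 genes. That interval treats genes of the same mice as replicates and leaves out the spread between mice, so it cannot decide on dilution. A difference between panels is argued against by the panel as a fixed block, where the mean of the 3 genes was -0.71 and all 3 passed (largest adjusted p = 0.0288). The authors' choice of reference genes is argued against by median-centred raw Cq, where the mean was -0.65 and all 3 passed (largest adjusted p = 0.0433). Fewer dendritic cells or T cells carrying these transcripts in tumor-bearing mice, or a lower activity of such cells, may be a biological explanation and remains a hypothesis.

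Single reactions lay more than 4 cycles from the median of their own group in 54 cases, in 13 samples, with 11 in replicate 26, 10 in replicate 14 and 8 in replicate 13. For 6 of these reactions the panel holds other assays of the same gene, and those 9 assays shifted in the same direction by a median of 0.06 cycles (2 by at least 1 cycle, the largest by 2.99), so a failed or spurious reaction in one well is a candidate explanation. Among the 54 are the fat cell genes Adipoq and Cfd in replicates 6, 8 and 9 and Retn in replicates 6 and 10. Lep and the second Fabp4 assay followed their mean across samples after group means were removed, with Pearson r of 0.84 (n = 25, permutation p = 1e-05, the smallest that 100000 resamples can give) and 0.62 (n = 28, permutation p = 0.0014; r = 0.47 without the 2 farthest samples). Different amounts of fat tissue taken with the implants may explain these, and no biological explanation was tested.

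Other splits of the samples into groups of the same sizes were tested for each count of calls. At day 14 the real split gave 14 calls and the highest of the other 99 splits gave 7. For the mean of the 3 days these were 14 and 2. No other split drawn reached either count (1 of 100 splits as large, the real one), which makes chance unlikely for both. The 100 splits are a part of the 6435 and 2574000 possible ones. They were drawn without regard to panel, so they do not separate condition from panels D and G. For tumor-bearing mice from day 7 to day 14, 3 of 100 splits gave at least the 1 call of the real split. The highest other count was also 1, so chance is not excluded for a single call that other splits gave too. For days 7 and 21 and for both changes from day 7 to day 21 within a condition, 10 splits are too few for a share under 0.05; real and highest other counts were 0 and 0 (10 of 10 splits as large), 7 and 1 (1 of 10), 0 and 0 in healthy mice (10 of 10), and 3 and 0 in tumor-bearing mice (1 of 10).

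In healthy mice, 17 of 100 splits gave at least the 2 calls of day 21 minus day 14, with up to 24, so chance cannot be excluded for that count. Where the real count is 0, every split gives at least as many (100 of 100), so the splits say nothing about chance. This holds for the differences of the tumor effect between days (highest other 1, 4 and 1), for healthy mice from day 7 to day 14 (highest other 36) and for tumor-bearing mice from day 14 to day 21 (highest other 13). The splits with 36, 24 and 13 calls point to a structure of the samples, whose source was not tested.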

How the results depend on the processing

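The alternatives without outlying reactions and without 4 samples (healthy 13 and 14, tumor-bearing 21 and 26) were tests chosen after seeing the data. No paired analysis was possible because no replicate number is shared between groups; the pairs on the same panel are different mice that share a panel, which entered as a block. Of the comparisons of a named gene with another setting, 610 kept direction and side of the threshold, 103 kept direction but no longer passed, 3 newly passed and 8 reversed. With 1 sample left out, 806 were the same, 143 no longer passed and 6 newly passed. Of the counts and list values, 218 were the same under other settings 52 moved and 1 no longer passed; with 1 sample left out, 242 were the same, 37 moved and 1 reversed.

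The neutrophil list passed at day 14 under every setting run, with a mean of 1.13 (assays measured in all 28 samples) to 3.84 (missing reactions at the largest Cq). At day 21 it was 0.73 and no longer passed with assays measured in all 28 samples, where fewer members are tested. Ccr7, Ccl5, Chi3l3 and S100a9 passed for the mean of the 3 days in every other setting run, and Ccl22 in every one but the largest Cq (-2.53, adjusted p = 0.699). The cause of the changes that follow was not tested, except where fewer assays or samples are named.

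With missing reactions set to the largest Cq, the calls were 4 at day 14, 0 at day 21 and 4 for the mean; 1 for the change of the tumor effect from day 7 to 14; in healthy mice 1 (day 14 minus 7), 0 (21 minus 14) and 1 (21 minus 7); in tumor-bearing mice 0 (14 minus 7) and 1 (21 minus 7); and 2 lists for the mean. Direction reversed under it for Bmp15 (0.48) and Ghrl (0.57) at day 14, for the change of the tumor effect of Hrh1 from day 7 to 14 (0.60) and of Il19 (-1.58), Bmp15 (-3.29) and Fabp4 (-7.69) from day 14 to 21, and for Cxcr4 (-3.115) and Fabp4 (-4.26) in tumor-bearing mice from day 14 to 21.

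With only assays measured in all 28 samples, which tests fewer assays, the calls were 3 at day 14, 1 at day 21 and 6 for the mean, 0 in healthy mice (21 minus 14), 0 and 0 in tumor-bearing mice (14 minus 7, 21 minus 7), with 1 list at day 7 and 2 at day 21. With a mean Cq of at most 28 they were 4 at day 21, 4 in healthy mice (21 minus 14) and 0 in tumor-bearing mice (14 minus 7), and detection at that limit called 1 assay at day 14.

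With the panel as a fixed block, the tumor effect changed for 1 (14 minus 7), 1 (21 minus 14) and 2 assays (21 minus 7); healthy mice had 1 (14 minus 7) and 1 (21 minus 14), tumor-bearing mice 3 (14 minus 7), and 2 lists passed for the mean. Without the panels that hold 1 group, with fewer samples, these were 1 and 1 for the tumor effect (14 minus 7, 21 minus 14), 2 and 5 in healthy mice (14 minus 7, 21 minus 14), 3 in tumor-bearing mice (14 minus 7) and 3 lists for the mean. With only the panels that hold 1 group (4 against 4), limma called 0 assays at day 14. With no panel block, healthy mice had 4 calls (21 minus 14). A separate fit per day gave 6 at day 14.

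Raw Cq centred on the housekeeping genes gave 4 calls in healthy mice (21 minus 14) and 2 in tumor-bearing mice (14 minus 7); median-centred raw Cq gave 2 in the latter and 1 list at day 7. The trend and robust prior gave 3 in tumor-bearing mice (14 minus 7). With an estimated inter-gene correlation 1 list passed at day 21 and 1 for the mean, and with fry, which uses fewer members, 0 and 1. Without reactions over 4 cycles from their group median, 1 assay changed its tumor effect from day 7 to 14. Without the 4 samples, 1 assay changed its tumor effect from day 14 to 21, healthy mice had 2 (14 minus 7) and 20 calls (21 minus 14), and 1 list passed at day 7. Among these 20 calls were rises of S100a9 (log2 difference 1.76) and of both S100a8 assays (2.55 and 2.24), and a fall of F3 (-1.09).

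Leaving out 1 sample gave 8 to 15 calls at day 14, 1 to 7 at day 21 and 8 to 15 for the mean; 0 to 1 for the tumor effect from day 7 to 14 and 0 to 1 from day 7 to 21; in healthy mice 0 to 1 (14 minus 7) and 0 to 15 (21 minus 14); in tumor-bearing mice 1 to 3 (14 minus 7) and 0 to 9 (21 minus 14). Lists past the threshold were 0 to 3 at day 7, 2 to 6 at day 21 and 2 to 6 for the mean. The neutrophil list at day 7 had a mean of -0.0215 to 0.46, negative without tumor-bearing replicate 4.

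Late or missing reactions limit the genes of low abundance. Prtn3 had 3 values and Itgb2l 1 in the 8 healthy samples of day 14. The Prtn3 difference thus rests on the healthy samples that gave a Cq, and Itgb2l was not tested at that day. A Cq of at most 28 was found at day 14 for Camp in 2 of 8 healthy and 8 of 8 tumor-bearing samples. For Ela2 it was found in 0 of 8 and 6 of 8, and at day 21 in 0 of 3 and 3 of 3. The healthy values behind the Camp and Ela2 rises at day 14 are therefore mostly late or missing.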

Other observations

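The test in this part was chosen only after the result was seen.

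Granule protein genes such as Camp, Ltf and Ela2 are transcribed mainly by neutrophil precursors, while S100a8, S100a9, Il8rb and Fpr1 are also transcribed by mature cells. A score of the mean of the first set minus the mean of the second was -4.13 ± 0.8 (SD, n = 7) at day 14 and -2.74 ± 0.58 (SD, n = 3) at day 21 in tumor-bearing mice, a difference of 1.38 (exact permutation p = 0.0333, two-sided, over 120 splits, of which the smallest possible is 0.00833). The ranges overlap, at -5.43 to -2.93 for day 14 and -3.3 to -2.15 for day 21. In healthy mice the score was -6.23 ± 1.49 (SD, n = 3) and -6.98 ± 0.3 (SD, n = 3). Both sets of genes were chosen after their values were seen, and Prtn3, also a granule gene of precursors, was not among them. The p therefore cannot decide whether the share of precursor transcripts differed, and most day 14 samples were run on other panels than those of day 21.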
